A study of Populus x canadensis with 4 samples.

How the data were processed

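Leaf small RNA of the poplar Populus × euramericana 'Neva' was sequenced after 3 days at 0, 2, 4 or 8 mM para-hydroxybenzoic acid. Per the labels' protocols, equal parts of RNA of the same treatment were mixed before the library was made, which left 4 libraries, 1 per dose. Base calls were converted with bcl2fastq 1.8.4, per the submitters' processing notes. The read mapper, the counting tool, the genome build and the microRNA annotation are not given in the sources used here.

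The deposited table has 738 rows with 578 names and, per the file headers, a raw and a normalized value for every library. The raw values are estimated counts as the authors deposited them, and many are fractions. The normalized values, a linear signal deposited by the authors, equal the raw value times 1 factor per library, 1.356, 0.986, 0.833 and 0.891 at 0, 2, 4 and 8 mM. They are not divided by sequence length or scaled to a fixed library total. The factors lie close to those of the median of ratios, which came to 1.355, 0.970, 0.825 and 0.884 here. In the authors' deposited table a text line separates 447 sequences at p of at most 0.05 from 82 others. The test behind it is not named in the file and it was not used here.

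The rows list 529 distinct sequences. Rows that repeat a sequence hold equal values, read here as equal shares of its reads. Of 134 sequences in 2 rows, 10.4% had whole raw values within 0.002 in every library when 1 row was read and 88.1% when both were summed. Rows were therefore summed per sequence, a choice made after the table was seen, with a single row used once as an added alternative. Families were taken from the number in each name. Names come from the file alone: 281 sequences carry a Populus trichocarpa name, 204 the name of another species and 44 a candidate name. A suffix such as _R+1 or 1ss19GC is read here as a form that differs from the listed microRNA in its ends or at a base, and p3 or p5 after MIR as an arm of the hairpin. Near-identical members cannot be separated by counting, so many results are given for family totals. A total sums all sequences with the same family number. It can include unlike sequences, such as the other arm of a hairpin, which can move in the other direction. Of 407 sequences with at least 20 reads, 6 had the same values as another sequence. 2 sequences had names of 2 families.

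The comparisons, filter, lists and naming rule were fixed before the data were examined. Log2 ratios were taken on log2(value + 1), which understates differences of scarce sequences, for the 350 sequences with a mean of at least 10 over the 4 libraries. Sequences at least 2-fold higher or lower were counted. With 1 library per dose no p-value was computed. Folds given with intervals are plain ratios of normalized values with an exact 95% conditional binomial interval from the raw counts, rounded to whole reads. Shares of reads have Wilson intervals. A count of 0 was replaced by 3 counts in its library for a lower bound on a fold, with the other count taken as it stands. No family total lay between 0 and 5 reads, so a listed 0 may stand for a few reads that were cut. Counting noise alone was simulated 1000 times, by Poisson draws around the mean level of each sequence over the 4 libraries at the depth of each library. The draws applied no cutoff at low counts, so the noise-only numbers may be too low for scarce sequences. List medians were placed among 10000 random lists of the same size matched on mean level. Intervals of list medians are 95% order-statistic intervals over the members. Random lists were drawn sequence by sequence, so related members of a family were treated as separate and percentiles can look too extreme. Setting members with 0 reads in 1 of the 2 libraries to their bound left the list medians in place except for 2 of the 30 medians, which moved by at most 0.05. By the rule fixed beforehand a member with 0 reads in both libraries enters with a log2 ratio of 0, which concerned 2 of the 30 medians, both of the phosphate and sulphate list, and leaving it out was added after the data were seen.

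The lists were auxin, copper and laccase, phosphate and sulphate, leaf development, disease resistance, small RNA machinery, phenylpropanoid MYB, pentatricopeptide repeat, narrowly conserved families and predicted candidates. Their members miR857, miR165, miR474, miR480 and miR1445 had no value among the sequences analysed here. By the naming rule the text could give the 6 sequences with the highest and the 6 with the lowest ratio at each dose, the most abundant member of each listed family or the family itself, and the 3 with the largest difference in each direction among those that followed the dose. Transfer and ribosomal RNA-like families were picked after the table was seen.

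The procedure was tested on simulated data for 8 against 0 mM with 350 sequences, of which 200 were changed 4-fold to 5-fold, in 20 draws. It recovered 98.6% of the changed sequences past 2-fold and placed 1.97% of the unchanged ones past 2-fold, and 95.7% of the intervals held the true ratio. The draws held counting noise only. Changes between 2-fold and 4-fold and variation between plants or libraries were not simulated. Of 200 simulated lists of 17 unchanged sequences, 7.5% fell below percentile 5 (exact 95% interval 4.26 to 12.1), with a mean percentile of 48.1. Of 2000 further lists, drawn after that value was seen, 5% did (4.09 to 6.05). Both sets used values independent between sequences, so they do not test lists of related members. Alternatives were 3 other scalings (median of ratios, equal table totals, and equal totals without the 10 most abundant sequences), pseudocounts of 0.1 and 10, no filter, a filter of 50, rows as deposited, family totals, and thresholds of 1.5-fold and 4-fold. Added after the data were seen were a single row per sequence, libraries thinned to the smallest total, Populus names and candidates only, a set without transfer and ribosomal RNA-like names, and lists without members that had no reads in either library. Genome coordinates were not analysed here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.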

Results

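MicroRNAs were measured in leaves of the hybrid poplar Populus × euramericana 'Neva' after 3 days in culture solution holding 0, 2, 4 or 8 mM para-hydroxybenzoic acid, a phenolic acid that can hold back plant growth. The comparison asks how leaf microRNA levels differ with the dose. Equal parts of RNA from plants of one treatment had been mixed, so each dose was 1 library. No difference reported here therefore has a replicate check, and the spread between plants is not known. The table held 529 distinct mature sequences from 120 named families and 44 predicted candidates. Reads assigned to them came to 2640653 at 0 mM, 4998878 at 2 mM, 6369127 at 4 mM and 5310499 at 8 mM. Of the sequences, 409, 438, 445 and 441 were detected at 0, 2, 4 and 8 mM. Taken as at most 3 reads, a count of 0 allows a normalized read count of up to 4.07, 2.96, 2.50 and 2.67 in these libraries. No family total lay between 0 and 5 reads, so low counts may have been cut before deposit. The words "0 reads" therefore mean a listed 0, and "at least" values and intervals from such a 0 may start too high. Folds other than the "at least" values carry exact 95% intervals for counting error. These cover counting error only, and reads amplified by PCR without molecular identifiers are not independent molecules. Where 1 of the libraries had 0 reads, the "at least" values put 3 counts in its place and take the other count as it stands, so that the exact interval can start lower, at 40.2-fold for the 50.5-fold of ptc-MIR319d-p5 at 4 mM and at 5.56-fold for the 7.27-fold of PC-3p-102599_40 at 2 mM. Levels are the authors' normalized read counts. A fold given for a family is that of the sum of all sequences with its number, both hairpin arms included where listed. Genome positions of the hairpins were not used here.

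Most reads came from 3 families whose members are known to target disease resistance genes of the nucleotide-binding, leucine-rich repeat type. miR472, miR482 and miR1448 together held 64.5% of the reads at 0 mM (Wilson 95% interval 64.4 to 64.5), 69.9% at 2 mM (69.9 to 70.0), 74.9% at 4 mM (74.8 to 74.9) and 67.9% at 8 mM (67.9 to 68.0). miR472 held 35.0% of the reads at 0 mM and 49.5% at 4 mM, while miR482 held 15.8% and 11.02%. The most abundant sequence at every dose was ptc-miR472a, at 22.3%, 24.6%, 28.0% and 26.4% of the reads. miR166, which targets class III homeodomain leucine zipper genes, held 15.1%, 14.1%, 11.4% and 16.03%. Sequences of 22 nt, the length of the most abundant miR472, miR482 and miR1448 forms, held 65.6%, 71.6%, 76.6% and 69.6% of the reads, and sequences of 21 nt held 31.9%, 27.3%, 21.9% and 29.0%. A 5′ T was found in 94.7%, 97.2%, 97.3% and 97.2% of the reads.

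The untreated library held the largest share of 18 nt sequences and of names that resemble fragments of other RNA. Sequences of 18 nt made up 0.526% of its reads, against 0.0432%, 0.0694% and 0.0865% at 2, 4 and 8 mM. At 0 mM gma-miR6300 alone held 12049 of the 13892 reads of 18 nt, so this share largely overlaps with the next. Families whose listed sequences resemble ends of transfer or ribosomal RNA (miR6300, miR8175, miR5368, miR2916 and miR6478) made up 1.96% of its reads, against 0.725%, 1.26% and 1.17%. The most abundant of them, miR6300, stood at 51618, 16657, 44511 and 32172 normalized read counts. The next, miR5368, went the other way, at 15213, 17549, 21000 and 21805. The 10 most abundant sequences held 82.1% of the reads at 0 mM and 85.9%, 88.4% and 87.0% at 2, 4 and 8 mM.

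**Figure D1:**
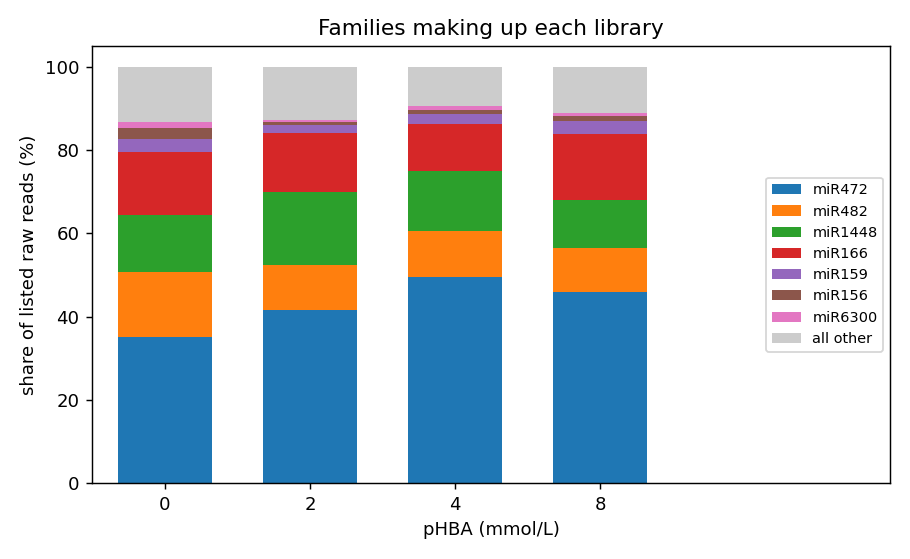
Stacked bars give the percent of the listed raw reads held by miR472, miR482, miR1448, miR166, miR159, miR156, miR6300 and all other families, 1 library per dose of para-hydroxybenzoic acid (pHBA, mmol/L). miR472 takes the largest share at every dose, from 35.0% at 0 mM to 49.5% at 4 mM.

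At 2 mM, miR398, miR408 and miR1444, families tied to copper use, were higher than in the untreated library, while miR156, miR168 and miR827 were lower. miR398, which targets copper/zinc superoxide dismutases, was 1.79-fold higher (1.75 to 1.82), and miR408, which targets plantacyanin and laccase genes, was 1.53-fold higher (1.504 to 1.56). miR396, which targets growth-regulating factors, was 2.32-fold higher (2.29 to 2.35), and miR319, which targets TCP transcription factors, was 2.16-fold higher (2.00 to 2.33). Equal table totals, which lower log2 ratios at 2 mM by 0.46, left at most 0.38 for the copper families. They put miR396 and miR319 below 2-fold. miR168, which targets AGO1, was 2.59-fold lower (2.54 to 2.64), and miR156, which targets SPL transcription factors, was 2.20-fold lower (2.17 to 2.22). miR827, which targets genes with an SPX domain, was 3.34-fold lower (2.94 to 3.79).

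Of the 17 copper and laccase sequences that were measured, 3 were at least 2-fold higher at 2 mM, 0 were at least 2-fold lower and 14 lay between. With equal table totals 2 were higher and 1 lower. Their median log2 ratio was 0.58 (0.12 with equal table totals), at percentile 97.5 among 10000 random lists of the same size matched on mean level, a description of these libraries. The interval of that median over the members was -0.01 to 0.82. miR1444, which targets polyphenol oxidases, was 1.498-fold higher (1.48 to 1.52). miR397, which targets laccases, was 1.35-fold higher (1.24 to 1.46), but with libraries set to equal table totals its log2 ratio was -0.03. Of the 8 phosphate and sulphate sequences, ptc-MIR399b-p5 had 0 reads at both 0 and 2 mM and so no ratio. Among the other 7, 2 were higher, 3 lower and 2 between, with a median of -0.94 (percentile 8.76). Counting the empty member as a ratio of 0 gave -0.47 (interval -3.38 to 2.89, percentile 22.8). Equal table totals gave -1.46, but the filter was applied again after that scaling and ptc-MIR399b-p5 dropped out, so the members differ. Without the filter on low levels the median was 0.20. miR399, which targets the phosphate regulator PHO2, was 1.98-fold lower (1.66 to 2.36), whereas miR395, which targets genes of sulphate assimilation, was 3.28-fold higher (2.26 to 4.88) on a level of only 47.5 normalized read counts at 0 mM. miR2111 did not pass the filter and is not among the 8. It was listed at 0 reads at 0 mM and at 21.7, 8.33 and 4.46 normalized read counts at 2, 4 and 8 mM.

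The leaf development list had 23 sequences higher, 24 lower and 48 between at 2 mM, with a median of 0.08 (percentile 66.1, but -0.38 with equal table totals). Besides miR396 and miR319, miR394, which targets an F-box gene of the shoot apex, was 2.03-fold higher (1.96 to 2.11), but below 2-fold with equal table totals. The most abundant miR156 sequence, ptc-miR156g, was 3.02-fold lower (2.98 to 3.07), and nta-miR156a_R+2 had 30 reads at 0 mM and 0 at 2 mM, at least 13.8-fold lower. The related miR157 was 4.13-fold lower (1.79 to 10.6). Of the 33 auxin sequences, 7 were higher, 5 lower and 21 between (median 0.16, percentile 67.8, but -0.33 with equal table totals). Among them miR167, which targets auxin response factors, was 1.67-fold higher (1.65 to 1.70), miR390, which triggers processing of the TAS3 precursor, was 1.64-fold higher (1.41 to 1.91), and miR160, which targets other auxin response factors, was 1.22-fold lower (1.17 to 1.27). Of the 15 sequences of the small RNA machinery list, 3 were higher, 6 lower and 6 between (median -0.44, percentile 6.74). miR162, which targets DCL1, went the other way from miR168 and was 1.98-fold higher (1.93 to 2.02).

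The disease resistance list had 1 of 20 sequences higher, 3 lower and 16 between at 2 mM, with a median of 0.15 (percentile 50.1, but -0.31 with equal table totals) and a mean of the other sign, -0.02. In abundance, miR472 was 1.64-fold higher (1.63 to 1.64), miR1448 1.78-fold higher (1.77 to 1.79) and miR482 1.08-fold lower (1.07 to 1.08). The 3 sequences of the phenylpropanoid MYB list had a median of 0.44 (percentile 70.9, but -0.02 with equal table totals), with 1 higher, 0 lower and 2 between. The pentatricopeptide repeat list had 1 of 8 higher, 0 lower and 7 between (median 0.16, percentile 57.2, but -0.29 with equal table totals). The narrowly conserved families had 11 of 60 sequences higher, 7 lower and 42 between (median 0.06, percentile 54.1, but -0.40 with equal table totals). Among these, miR481 was 7.25-fold higher (5.78 to 9.20), with ptc-MIR481d-p5 24.5-fold higher (10.3 to 76.6) from 5 reads at 0 mM, and miR473 was 1.99-fold lower (1.93 to 2.06). The 27 predicted candidates come from the authors' own table, so the list is no independent evidence of a direction. Of them 12 were higher, 2 lower and 13 between (median 0.69, interval -0.10 to 1.45, percentile 96.6). PC-3p-102599_40 and PC-3p-70722_70 had 0 reads at 0 mM and were at least 7.27-fold and 7.03-fold higher at 2 mM. Also among the 6 highest were mdm-MIR396d-p3 (at least 5.57-fold higher), mtr-miR166c_L+5R-2 (at least 4.85-fold higher) and gma-MIR4995-p3_1ss19GC (23.0-fold higher, 9.64 to 71.7, from 5 reads). Among the 6 lowest were PC-3p-71534_69 (13.8-fold lower, 5.52 to 44.2) and gma-miR6300 (10.8-fold lower, 10.2 to 11.4). The longer forms gma-miR6300_R+1_2, gma-miR6300_R+1_3 and gma-miR6300_R+1_1 had 0 reads at 2 mM, at least 14.7-fold, 14.7-fold and 7.34-fold lower. Their reads at 0 mM, 32, 32 and 16, stood over 2, 2 and 1 rows, equal per row. These forms may therefore be 1 pool of reads, and their bounds differ only with the number of rows.

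Across the 350 sequences with a mean of at least 10 normalized read counts, 73 were at least 2-fold higher at 2 mM and 83 at least 2-fold lower, and counting noise alone gave means of 3.07 and 2.57. Noise-only means here and below may be too low, since low counts were kept in the simulation but may have been cut from the deposited values. The interval excluded 1 for 70 and 81 of them. With equal table totals, which lower log2 ratios to 0 mM by 0.46, 0.57 and 0.40 at 2, 4 and 8 mM, less for scarce sequences, the split was 42 higher and 114 lower.

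At 4 mM, the copper families were lower than in the untreated library and than at 2 mM. miR397 was 7.27-fold lower (6.26 to 8.48), miR398 3.92-fold lower (3.80 to 4.04), miR408 2.96-fold lower (2.88 to 3.04) and miR1444 1.99-fold lower (1.95 to 2.03). The phosphate families miR827 and miR399 were 6.52-fold (5.60 to 7.62) and 3.07-fold (2.53 to 3.73) lower, and miR319, higher at 2 mM, was 3.40-fold lower (3.02 to 3.82). miR168 was 3.42-fold lower (3.35 to 3.49). miR472 was 2.09-fold higher (2.09 to 2.10), from 1255111 to 2627566 normalized read counts, and miR167 was 2.06-fold higher (2.03 to 2.09). Equal table totals, which lower log2 ratios at 4 mM by 0.57, put both below 2-fold. The miR472 share of reads went from 35.0% to 49.5%.

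Of the 17 copper and laccase sequences, 16 were at least 2-fold lower at 4 mM, 0 were higher and 1 lay between. The median log2 ratio was -1.87, below the medians of all 10000 matched random lists (percentile 0), and it was -2.42 with equal table totals. The members belong to miR397, miR398, miR408 and miR1444 and are not independent, whereas random lists drew single sequences, so the percentile can overstate how unusual the list is. ptc-MIR397a-p3 and ptc-miR397b_L-1 had 0 reads at 4 mM and were at least 15.7-fold and 10.04-fold lower, while ptc-miR398b went from 17252 to 4321 normalized read counts and ptc-miR408-3p from 18981 to 6448. ptc-MIR399b-p5 had no ratio at 4 mM either. Of the other 7 phosphate and sulphate sequences 1 was higher, 4 were lower and 2 lay between, with a median of -1.61 (percentile 1.11). With the empty member at 0 the median was -1.13 (interval -6.36 to 2.10, percentile 5.85). Equal table totals gave -2.64 on members filtered again after that scaling, without ptc-MIR399b-p5. ptc-MIR399e-p5 had 60 reads at 0 mM and 0 at 4 mM, at least 32.6-fold lower. miR395 was 2.28-fold lower (1.33 to 3.97).

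The leaf development list had 17 sequences higher, 23 lower and 55 between at 4 mM, with a median of 0.07 (percentile 54.5, but -0.49 with equal table totals) and a mean of -0.09. ptc-MIR319d-p5 had 93 reads at 0 mM and 0 at 4 mM, at least 50.5-fold lower. miR156 was 1.72-fold lower (1.70 to 1.74), and miR164, which targets NAC transcription factors, was 1.53-fold lower (1.502 to 1.55). miR396 was 1.32-fold higher (1.31 to 1.34), a direction that turned with equal table totals (log2 ratio -0.16). The auxin list had 7 higher, 6 lower and 20 between (median -0.17, percentile 18.8), with hex-MIR390b-p5_2ss8AG21GT at least 6.14-fold higher from 0 reads. The miR390 total was 1.22-fold lower (1.03 to 1.45). miR160 was 1.47-fold lower (1.41 to 1.54). The small RNA machinery list had 4 higher, 6 lower and 5 between (median -0.09, percentile 28.9). miR162 was 1.96-fold higher (1.92 to 2.01), and ptc-MIR403b-p5, from a family that targets AGO2, had 0 reads at 4 mM and was at least 14.1-fold lower. The miR403 total was 1.12-fold higher (1.07 to 1.17), but lower with equal table totals (log2 ratio -0.41).

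Of the 20 disease resistance sequences, 4 were higher, 3 lower and 13 between at 4 mM (median 0.16, percentile 62.1, but -0.40 with equal table totals). miR828, which targets MYB genes of the phenylpropanoid pathway, was 2.23-fold lower (1.55 to 3.23), and its list had 2 of 3 lower, 0 higher and 1 between (median -1.31, percentile 12.9). The pentatricopeptide repeat list had 1 of 8 higher, 0 lower and 7 between (median 0.37, percentile 75.9, but -0.19 with equal table totals). In it miR475 was 1.59-fold higher (1.55 to 1.62), a log2 ratio of 0.67 that equal table totals lower by 0.57. The narrowly conserved families had 13 of 60 higher, 3 lower and 44 between (median 0.39, percentile 98.5, but -0.18 with equal table totals). miR481 was 8.58-fold higher (6.87 to 10.9), including ptc-MIR481c-p5_1ss23AG at 30.2-fold (12.8 to 93.9), ptc-MIR7836-p3 was at least 9.21-fold higher from 0 reads, and miR6445 was 1.90-fold higher (1.83 to 1.98). Among the predicted candidates 13 of 27 were higher, 2 lower and 12 between (median 0.95, interval -0.003 to 2.21, percentile 99.9). PC-5p-44713_134 led them, at least 17.2-fold higher from 0 reads. ath-miR8175_L-1_1ss2AT had 0 reads at 4 mM, at least 14.1-fold lower.

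In all, 66 of 350 sequences were at least 2-fold higher at 4 mM and 90 at least 2-fold lower, with noise-only means of 2.96 and 2.03. The interval excluded 1 for 62 and 89 of them, and equal table totals gave 36 higher and 127 lower.

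At 8 mM, the copper families were again lower than in the untreated library, by less than at 4 mM. miR397 was 2.58-fold lower (2.32 to 2.87), miR408 1.97-fold lower (1.93 to 2.02), miR398 1.89-fold lower (1.84 to 1.94) and miR1444 1.47-fold lower (1.44 to 1.49). miR827 was 4.52-fold lower (3.95 to 5.18), miR399 2.85-fold lower (2.35 to 3.46) and miR319 2.66-fold lower (2.38 to 2.97). miR162 was 1.93-fold higher (1.89 to 1.98) and miR167 1.75-fold higher (1.72 to 1.77).

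Of the 17 copper and laccase sequences, 7 were at least 2-fold lower at 8 mM, 0 higher and 10 between (median -0.95, percentile 0.22). With equal table totals 12 were lower (median -1.35). The phosphate and sulphate list had 5 of 8 lower, 2 higher and 1 between (median -1.72, interval -6.36 to 5.36, percentile 0.07). Its mean of -0.83 was smaller because members of miR399 went apart: ptc-miR399f was 4.41-fold lower (3.06 to 6.49) and ptc-MIR399e-p5 at least 30.4-fold lower, whereas ptc-miR399b was 5.07-fold higher (2.30 to 13.2) from 7 reads and ptc-MIR399b-p5 at least 9.86-fold higher from 0 reads. The leaf development list had 17 higher, 19 lower and 59 between, with a median of 0.11 (percentile 80.1, but -0.32 with equal table totals) and a mean of -0.03. In it miR156 was 1.57-fold lower (1.55 to 1.59) and miR164 1.64-fold lower (1.62 to 1.67). miR166 was 1.41-fold higher (1.40 to 1.41), a log2 ratio of 0.49 that equal table totals lower by 0.40. ptc-MIR164c-p3 had 0 reads at 8 mM and was at least 7.61-fold lower. The auxin list had 3 higher, 5 lower and 25 between (median 0.13, percentile 77.3, but -0.30 with equal table totals). ptc-MIR160d-p3 was 12.3-fold lower (9.04 to 17.2), and miR393, which targets auxin receptors, stood at 15141 and 15261 normalized read counts at 0 and 8 mM.

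The small RNA machinery list had 1 of 15 higher, 4 lower and 10 between at 8 mM, with a median of 0.18 (percentile 69.7, but -0.22 with equal table totals) and a mean of -0.25. miR168 was 1.92-fold lower (1.88 to 1.95), and its sequence aau-miR168_L-3R-1_1ss22AT was 9.13-fold lower (3.51 to 30.1). The disease resistance list had 1 of 20 higher, 3 lower and 16 between, with a median of 0.06 (percentile 45.7, but -0.34 with equal table totals) and a mean of -0.15, and miR472 was 1.73-fold higher (1.73 to 1.74). The phenylpropanoid MYB list had 0 higher, 1 lower and 2 between (median -0.01, percentile 44.1), the lower one being ptc-miR828a, 3.31-fold lower (2.18 to 5.13). The pentatricopeptide repeat list had 2 of 8 higher, 0 lower and 6 between (median 0.57, percentile 92.3), with miR475 1.81-fold higher (1.77 to 1.85). The narrowly conserved families had 10 of 60 higher, 4 lower and 46 between (median 0.22, percentile 94.2, but -0.18 with equal table totals). Of these, miR481 was 3.05-fold higher (2.40 to 3.91), miR6439 2.14-fold higher (1.88 to 2.45), miR1446 1.78-fold higher (1.76 to 1.81) and miR6457 2.04-fold lower (1.93 to 2.16). Of the predicted candidates 8 of 27 were higher, 2 lower and 17 between (median 0.47, interval -0.20 to 1.05, percentile 98.2), with PC-5p-44713_134 at least 12.9-fold higher. ath-miR8175_L-2 was 8.60-fold lower (7.30 to 10.2) and nta-miR156a_R+2 9.13-fold lower (3.51 to 30.1).

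In all, 52 of 350 sequences were at least 2-fold higher at 8 mM and 75 at least 2-fold lower, with noise-only means of 2.84 and 2.27. The interval excluded 1 for 46 and 72 of them, and equal table totals gave 33 higher and 110 lower. In the plot of family totals by dose, the ratios that change sign with equal table totals, besides that of miR397 at 2 mM, are those of miR164 at 2 mM, miR393 at 2 and 8 mM, miR394, miR396 and miR403 at 4 and 8 mM, miR482 at 4 mM and miR1448 at 8 mM.

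**Figure D2:**
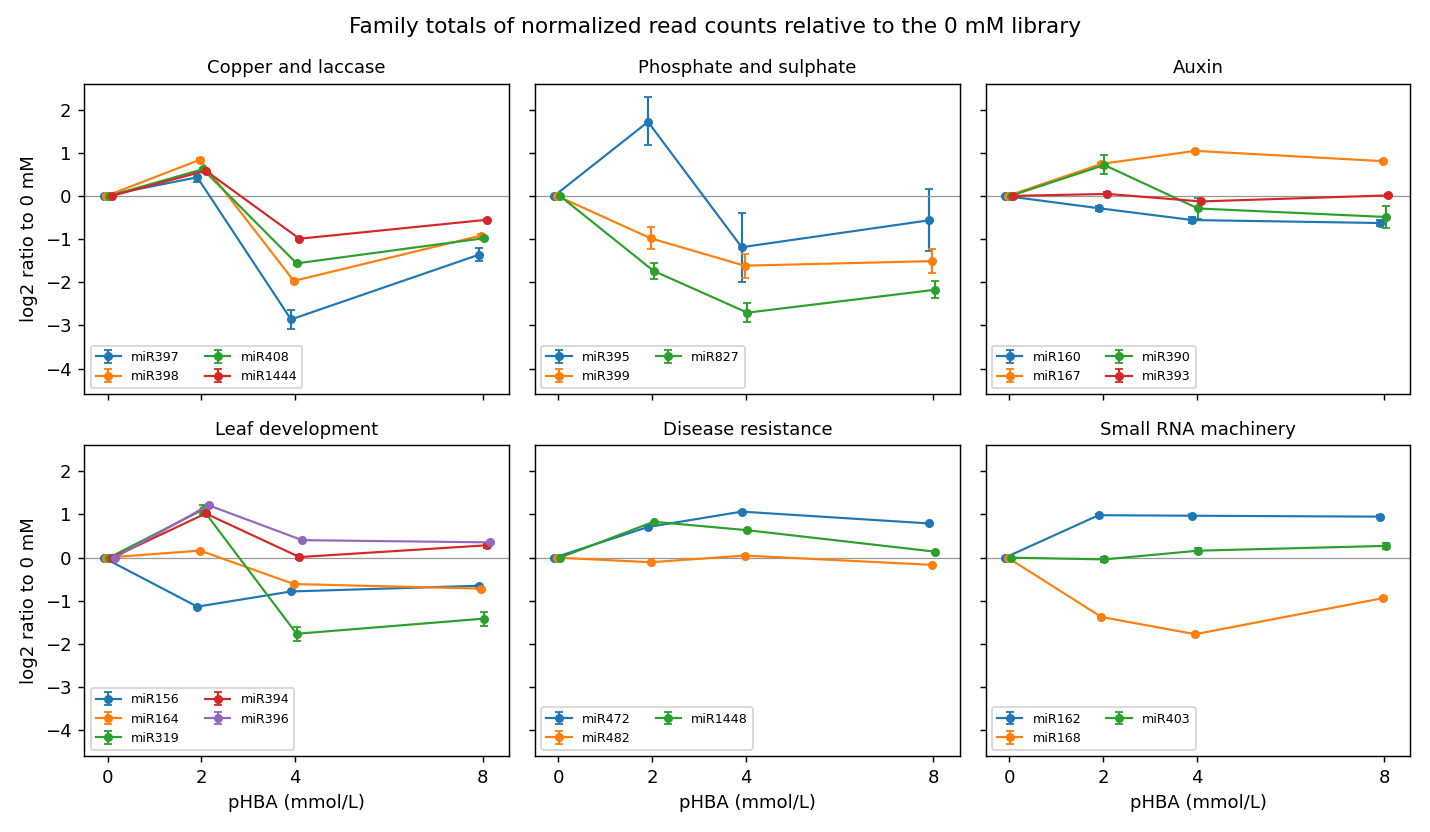
Log2 ratio of family totals of normalized read counts to the 0 mM library against the dose of para-hydroxybenzoic acid (mmol/L), 1 library per dose, with bars for the exact 95% counting intervals. miR397, miR398, miR408 and miR1444 lie above 0 at 2 mM, except miR397 with equal table totals (-0.03), and below 0 at 4 and 8 mM, lowest at 4 mM.

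The treated libraries were also compared with each other, which leaves the untreated library out. From 2 to 4 mM, miR397 was 9.80-fold lower (8.49 to 11.4), miR398 7.00-fold lower (6.80 to 7.21), miR408 4.53-fold lower (4.42 to 4.65) and miR1444 2.98-fold lower (2.93 to 3.03). miR395 was 7.48-fold lower (4.89 to 11.9), miR319 7.34-fold lower (6.63 to 8.16) and miR828 3.16-fold lower (2.29 to 4.40). miR394 and miR390 were each 2.01-fold lower (1.95 to 2.07 and 1.75 to 2.31). From 4 to 8 mM, miR397 was 2.82-fold higher (2.40 to 3.32), miR398 2.07-fold higher (2.01 to 2.14), miR168 1.78-fold higher (1.75 to 1.82), miR408 1.498-fold higher (1.46 to 1.54) and miR1444 1.36-fold higher (1.33 to 1.38). miR481 was 2.82-fold lower (2.51 to 3.17) at 8 than at 4 mM. Among the 350 sequences, 48 were at least 2-fold higher and 51 at least 2-fold lower at 4 than at 2 mM (noise-only means 1.66 and 1.53), and 29 were higher and 26 lower at 8 than at 4 mM (1.41 and 1.41). The interval excluded 1 for 47 and 50 of the first and for 24 and 25 of the second. Equal table totals gave 36 higher and 18 lower at 8 against 4 mM and moved the median of all sequences there from -0.03 to 0.13. Totals without the 10 most abundant sequences moved the median at 4 against 2 mM from 0.07 to 0.25.

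**Figure D3:**
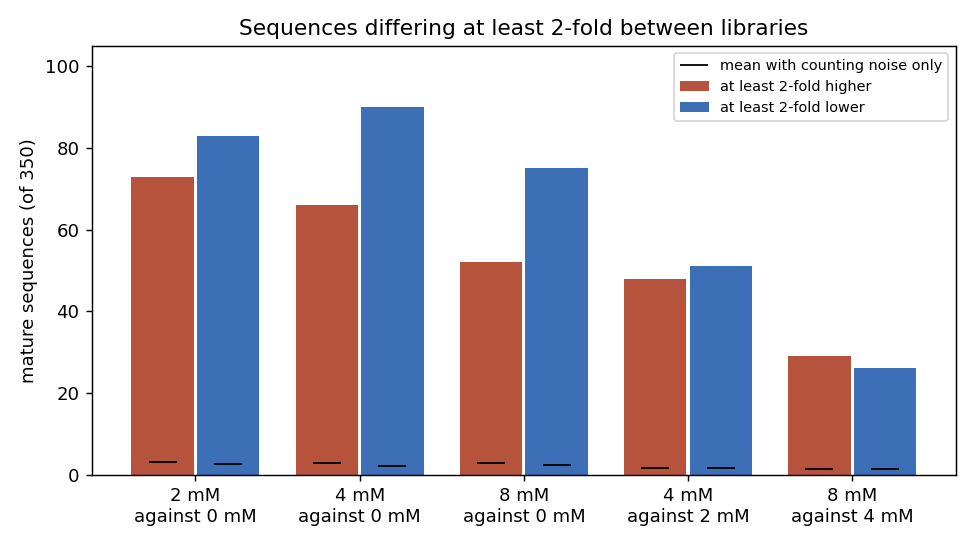
Number of the 350 sequences at least 2-fold higher and at least 2-fold lower in each comparison between single libraries (bars), with black marks for the mean number from counting noise alone. The 3 comparisons with the untreated library give 127 to 156 such sequences, that of 4 with 2 mM gives 99 and that of 8 with 4 mM gives 55.

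Few sequences followed the dose at every step. hpe-miR162a_R+3, a longer form of miR162, stood at 9.49, 40.4, 63.3 and 82.9 normalized read counts at 0, 2, 4 and 8 mM, ptc-miR399b at 9.49, 12.8, 44.1 and 48.1, and ptc-miR169u-3p_R-1, from a family that targets NF-YA genes, at 9.49, 16.8, 19.2 and 42.8. In the other direction, ptc-miR399e stood at 112.6, 58.2, 18.3 and 17.8, aau-miR168_L-3R-1_1ss22AT at 40.7, 24.6, 7.496 and 4.46, and ptc-MIR164c-p3 at 20.3, 17.7, 15.0 and 0. In total 17 sequences were higher at each step and 16 lower at each step, of which 6 and 13 differed at least 2-fold between 0 and 8 mM. Random order would give 14.6 in each direction.

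The 3 comparisons with the untreated library shared many sequences. At least 2-fold higher at 2, 4 and 8 mM alike were 33 sequences, where independent lists would share 2.05 and counting noise alone 0.844. At least 2-fold lower at all 3 doses were 37, against 4.57 and 0.094. With equal table totals 21 were higher and 68 lower at all 3 doses. For pairs of doses, 44 higher and 49 lower sequences were shared by 2 and 4 mM (independent lists 13.8 and 21.3, noise alone 1.36 and 0.314), 37 and 45 by 2 and 8 mM (10.8 and 17.8, noise alone 1.29 and 0.353), and 41 and 59 by 4 and 8 mM (9.81 and 19.3, noise alone 1.31 and 0.309). The covariance of the log2 ratios across sequences was 1.83 for 2 and 4 mM, 1.58 for 2 and 8 mM and 2.01 for 4 and 8 mM, against 0.0576, 0.0575 and 0.0578 with counting noise alone. All comparisons used the same single untreated library, which cannot be split, so part of each excess may come from that library. The noise-only values may also be too low, since the simulation applied no cutoff at low counts.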

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

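Alternatives with a single row per sequence, thinned libraries, Populus names and candidates only, no transfer and ribosomal RNA-like names, or no list members without reads in both libraries were chosen after the data were seen. Of 226 recomputed counts, 142 stayed within 1.5 times the reported count, and of 242 recomputed list medians, 232 stayed within the interval of the reported median. Many of these medians could not leave it. The 30 lowest and 30 highest medians with a member left out stay inside by construction. The 30 without transfer and ribosomal RNA-like names changed only the narrowly conserved list. Equal table totals moved 10 list medians and kept 20. Of 1338 recomputed ratios of single families and sequences, 420 moved out of their counting interval. No ratio or median of at least 2-fold changed sign, while smaller ones did, mostly with equal table totals. Other settings turned the medians of leaf development at 8 mM (-0.10) and disease resistance at 2 mM (-0.03) with rows as deposited, and of phosphate and sulphate at 2 mM (0.20) and phenylpropanoid MYB at 8 mM (0.40) with no filter, the last also with a member left out (up to 0.20). Among the scalings, equal table totals moved more counts and list medians than the others run, because treated libraries had larger totals after the authors' scaling. The filter, the threshold and family totals moved more of the counts. Counts of a few reads per sequence limit the scarce sequences.

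With equal table totals, 42, 36 and 33 sequences were higher at 2, 4 and 8 mM against the reported 73, 66 and 52, and 21 were higher and 68 lower at all 3 doses. Under the same scaling, families higher at 2 mM were 6 and lower 21, families higher at 4 mM were 5 and families lower at 8 mM were 27, and a pseudocount of 10 left 5 families higher at 8 mM. List medians under equal table totals were -0.33 and -0.76 for auxin at 2 and 4 mM, -0.38, -0.49 and -0.32 for leaf development at 2, 4 and 8 mM, -0.40 for disease resistance at 4 mM, -1.87 for phenylpropanoid MYB at 4 mM, and -0.40, -0.18 and -0.18 for the narrowly conserved families at 2, 4 and 8 mM. With the pseudocount of 10, 16 sequences were higher and 15 lower at 8 against 4 mM and 21 were higher at all doses, since it shrinks ratios of scarce sequences.

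Higher and lower counts at 2, 4 and 8 mM against 0 mM, then 4 against 2 and 8 against 4 mM, moved with the filter and the threshold, which change the number of sequences tested or the size required. With no filter, 137 were higher and 128 lower at 2 mM, 137 higher at 4 mM, 115 higher and 122 lower at 8 mM, 100 higher and 94 lower at 4 against 2 mM, 64 higher and 77 lower at 8 against 4 mM, and 57 higher and 67 lower at all doses. A filter of 50 gave 43 and 46, 34 and 52, 28 and 37, 21 and 26, and 8 and 7, with 17 and 23 at all doses. A 1.5-fold threshold gave 113, 106 and 93 higher at the 3 doses, 79 and 86 at 4 against 2 mM, 56 and 59 at 8 against 4 mM, and 63 higher and 63 lower at all doses. A 4-fold threshold gave 28 and 35, 27 and 32, 21 and 25, 11 and 26, and 9 and 5, with 16 and 7 at all doses.

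Counted as family totals, 12 were higher and 13 lower at 2 mM, 12 and 21 at 4 mM, 9 and 16 at 8 mM, 7 and 11 at 4 against 2 mM and 4 and 5 at 8 against 4 mM, with 5 and 7 at all doses and 5 rising and 5 falling at every step, since 87 families replaced 350 sequences. Populus names and candidates only, a smaller set, gave 44 and 38, 43 and 49, 32 and 39, 21 and 30, 18 higher at 8 against 4 mM, and 20 and 17 at all doses. Without transfer and ribosomal RNA-like names 31 were higher at 4 against 2 mM. With rows as deposited 27 rose at every step, since repeated rows count more than once. Reading 1 row per sequence put 22 nt sequences at 83.2%, 87.3%, 90.1% and 87.2% of the reads and miR472 at 44.7%, 51.2%, 58.7% and 57.9% at 0, 2, 4 and 8 mM, since miR166 and others listed in several rows then lose reads.

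No paired analysis was possible because each dose has 1 library.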

Other observations

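Some families outside the lists differed as much as those in them, and they are named here after their values were seen. miR1515 stood at 1607, 3916, 6211 and 5643 normalized read counts at 0, 2, 4 and 8 mM, 3.86-fold higher at 4 mM (3.63 to 4.11), and miR530 was 2.47-fold higher at 2 mM (2.33 to 2.61). miR1511 was 6.26-fold lower at 2 mM (4.78 to 8.29), 12.2-fold lower at 4 mM (8.76 to 17.4) and 7.38-fold lower at 8 mM (5.59 to 9.84). miR3627 was close to the untreated level at 2 mM, with 430 and 402 normalized read counts, and 3.94-fold lower at 4 mM (3.20 to 4.87). The 7 sequences with at least 2 copies of the plant telomere repeat, listed under miR8005 and miR8674, had 17.6 normalized read counts in sum at 0 mM and 131.6, 94.1 and 93.1 at 2, 4 and 8 mM, 7.46-fold higher at 2 mM (4.24 to 14.4). These directions held with equal table totals, which lower the log2 ratios by at most 0.57. The miR8674 sequences were listed at 0 at 0 and 2 mM, so the sums of the telomere repeat sequences may miss a few reads.

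The 2 strands of a hairpin did not always keep the same direction. Across the hairpins whose strands each had reads in at least 1 of the 2 libraries compared (28, 28 and 29 at 2, 4 and 8 mM), the log2 ratios of the known strand and of the other strand had Pearson's r of -0.11, 0.51 and 0.62 and Spearman's rho of -0.24, 0.22 and 0.30. The higher r at 4 and 8 mM rested on strands with 0 reads in 1 library: across the 28, 26 and 27 hairpins with reads of both strands in both libraries, r was -0.11, -0.06 and 0.17 and rho -0.24, 0.03 and 0.13. Those left out, MIR397a and MIR399e at 4 mM and MIR399b and MIR399e at 8 mM, had both strands in the same direction. This choice removes strands that moved together, so the lower r does not show that strands move apart. Hairpins are not independent replicates. ptc-miR472a was 1.52-fold higher at 2 mM (1.51 to 1.52) with a log2 ratio of 0.60, and the other strand of its hairpin had a log2 ratio of -1.47. For ptc-miR396a the values at 2 mM were 1.32 and -2.01.

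The tests of the 3 patterns that follow were all chosen after the results were seen. Each comparison with the untreated library gave more sequences at least 2-fold apart (156, 156 and 127 for 2, 4 and 8 mM) than any pair of treated libraries (100 for 8 and 2 mM, 99 for 4 and 2 mM, 55 for 8 and 4 mM), though the smallest of the first was only 1.27 times the largest of the second. At full depth, scaling by 1 factor per library is argued against as the whole cause, since the lowest such ratio under 3 other scalings was 1.26. These scalings were not run on thinned libraries. Depth stays open, because in 100 thinnings of all libraries to the smallest total the ratio averaged 1.16 (SD 0.0583) and went as low as 0.984. Breakdown of RNA in the untreated sample stays open too. That library held 0.526% of its reads at 18 nt against at most 0.0865% in the others. Of those 13892 reads, 12049 were gma-miR6300, a transfer RNA-like name. The shares of 19 and 20 nt were also largest at 0 mM, at 0.204% and 0.749%, against at most 0.189% and 0.421% in the others. Those of 21, 23 and 25 nt were largest there too, so the lengths do not settle whether reads were shorter in general. The ratio was 1.32 without the transfer and ribosomal RNA-like names, which does not show whether microRNAs were affected. The plants mixed and the acid itself cannot be told apart with 1 library per dose, so an effect of the treatment may be part of the difference but is untested.

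The copper families miR397, miR398, miR408 and miR1444 were together higher at 2 mM (miR397 not with equal table totals), lower at 4 mM and partly back at 8 mM. Their low level at 4 mM held under the other scalings, where the highest list median was -1.82, but the higher level at 2 mM shrank to a median of 0.12 with equal table totals, so a gain there cannot be told apart from the scaling. All 4 families moved in one direction at 3 of 3 dose steps, as did 0.65% of 10000 random sets of 4 from the 48 families with a mean of at least 500, a floor set after the values were seen so that miR397 was included; with equal table totals the step from 0 to 2 mM had 3 up and 1 down (-0.03). A candidate explanation is shared regulation, for which the copper-responsive activator SPL7 is known in other plants. The families were grouped by function beforehand, but neither copper nor SPL7 was measured, and 1 library per dose leaves the plants mixed as another source.

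miR6300 and miR8175 may be the ends of a single transfer RNA and not microRNAs. The first 7 bases of GTCGTTGTAGTATAGTGG (miR6300) pair at 7 of 7 positions with the bases before the last 4 of GATCCCCGGCAACGGCGCCA (miR8175). G with T was counted as a pair, and 1 of these positions is of that kind. By the same rule 2 of 12488 other pairs whose second sequence ends in CCA matched. CCA ends 8 of 10 miR8175 sequences against 16 of 519 others. A loss of all fragments of that RNA by 1 factor in treated leaves is argued against, because gma-miR6300, 18 nt long, and the 23 nt forms of the same end had log2 ratios to 0 mM of -3.43 and -1.17 at 2 mM, -2.35 and 0.36 at 4 mM and -2.20 and -0.16 at 8 mM. The gap to the miR8175 total depended on the form: for the miR6300 total it was 0.17, 2.09 and 1.66 at 2, 4 and 8 mM, and for gma-miR6300 alone 1.63, 0.05 and 0.14. A difference in how far the RNA was broken down, more short ends in the untreated sample, was not tested separately and stays open.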
